A study of Mus musculus with 38 samples.

How the data were processed

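The deposited table holds whole-number read counts per gene, in the unit counts, for 38 libraries of mouse CD4 T cells, with 24028 genes named by Entrez Gene numbers. Per the labels' protocols, naive CD4 T cells were isolated with a StemCell kit from pooled lymph nodes and spleen of single mice of either sex, and 24 h cultures were set on plates coated with anti-CD3 at 0.5 µg/ml and anti-CD28 at 0.2 µg/ml, with 50 U/ml interleukin-2. The authors extracted RNA with Trizol and a column kit, made stranded TruSeq libraries and read single ends of 76 nt on a NextSeq instrument. Per the submitters' processing notes, FastQC 0.11.5, STAR 2.5.2a, R 3.5 and edgeR 3.24.3 were used on mm10. The tool that counted reads and its gene annotation are not given in the sources used here, and the deposited counts carry no normalization. The table has 1 further column with a length per gene, which was not used.

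Each library was placed in one of 10 groups by its genotype and state as labelled. The labels state no sequencing batch and no link between a naive and a stimulated library. Gene symbols and GRCm38.p6 coordinates came from a RefSeq table, which matched 23968 identifiers; the others took 0.0749% of all counts. Genes were kept by edgeR's filterByExpr over the groups, which left 13650 genes. Library sizes were scaled by the trimmed mean of M values (TMM), and CPM values use the scaled sizes. A quasi-likelihood negative binomial model with a coefficient per group was fitted to all libraries (edgeR 4.0.16, R 4.3.3), and each of the 19 comparisons was a contrast tested two-sided by the quasi-likelihood F test. Every adjusted p of a gene is a Benjamini-Hochberg value over the tested genes of the comparison, and a gene was called below 0.05. The standard error of a log2 fold change is its size divided by the square root of its F statistic. The fold of a gene without counts in a group is a bound against 3 counts over the pooled group, which covers counting error only. Total counts per library lie between the values the report gives per group.

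The named genes were chosen by a rule set before the data were examined, as were the comparisons, lists and first set of alternatives. The rule took Cd28, Mir17hg and Gt(ROSA)26Sor. It took the 8 largest increases and decreases among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries (overlap was allowed for interactions), leaving out unnamed gene models and antigen receptor segments. It took up to 4 members with the smallest p from each list, and the 3 smallest p where no gene passed. The text prints some of these genes. Prl, Pomc and other genes of the closing section that the rule did not take, and levels of other genes given outside the comparisons where the rule took them were chosen after their values were seen. The simulated sets that kept the CD28ko-labelled difference and the estimated correlation in matched seed classes were added after the results were seen.

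The 23 gene lists tested were published miR-17~92 targets, calcineurin and NFAT, NF-kB, cytokines, activation surface markers, activation transcription factors, cell cycle, ribosome biogenesis, glycolysis, cholesterol, quiescence, PI3K brakes, amino acid, interferon-stimulated, apoptosis and helper lineage genes, and markers of B cells, myeloid cells, NK and CD8 cells, regulatory T cells, memory cells, red cells and RNA stress. Sex-linked and engineered genes were read only to check labels. Each list was compared with the other genes by camera with a correlation of 0.01 and again with an estimated correlation, adjusted by Benjamini-Hochberg over the lists of a comparison, and its members were also adjusted over the list alone. The rotation test fry was run beside it. Seed sites of the cluster's families were sought in the longest annotated 3' untranslated region of each gene (GENCODE transcripts), at least 30 bases long, with control heptamers of the same base composition and with classes matched on length and expression.

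Alternatives changed one choice at a time. They were DESeq2 size factors in the same fit (RLE), DESeq2 1.42.0 in place of edgeR, no filter on low counts, a filter at a mean of 5 CPM, only the libraries of the compared groups, the replicate number of the titles as a block over all groups, the same within genotype, a term for sex, and leaving out each library of the compared groups. For lists, seeds and reversal they were fry, the replicate block, longer seed sites, matched classes, an estimated correlation, a threshold of 0.01 and divided CD28ko-labelled libraries. Female libraries alone, all libraries without naive CD28ko-labelled 1 and naive rescue 2, and genes more than 10 Mb from the engineered loci were added after seeing the data. Regroupings of the compared libraries were counted in fits of those libraries alone; for stimulation responses, libraries of the same genotype and number were kept together. For naive rescue against naive CD28ko-labelled cells each regrouping was also scored by the correlation across genes of its log2 fold changes with those of naive T1792tg against wild-type.

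The methods were tested on simulated data, in which 100 genes per size were changed in counts drawn from a negative binomial model with a mean per gene. For CD28ko-labelled against wild-type at 24 h, 55% of genes changed 1.5-fold and 83% of those changed 2-fold were called with the right sign, and 6.1% of calls were unchanged genes. For rescue against CD28ko-labelled these values were 58%, 76% and 5.6%, and for the CD28ko-labelled interaction 35%, 61% and 4%. A list of 20 genes shifted 1.3-fold had a camera p of 2.0e-34, and 2 of 50 unshifted lists had a p under 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and camera and fry came with limma 3.58.1.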

Results

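Naive CD4 T cells were enriched from the pooled lymph nodes and spleens of single mice, and the polyA RNA of each preparation was sequenced and counted per gene. One part of the libraries came from cells taken directly (naive) and the other from cells kept for 24 h on plates carrying antibodies to CD3 and CD28 with interleukin-2 in the medium. The antibodies engage the T cell receptor complex and the main costimulatory receptor of naive T cells. The 38 libraries covered 5 genotypes. These were wild-type mice, mice labelled CD28-/- (called CD28ko-labelled), mice in which Cd4-driven Cre recombinase deletes a floxed miR-17~92 microRNA cluster (T1792del), mice in which the same Cre switches on a miR-17~92 transgene in the Rosa26 locus (T1792tg), and CD28-/- mice with that Cre and transgene (rescue). The miR-17~92 cluster encodes microRNAs that promote lymphocyte growth and survival. No genotype was labelled as carrying Cre alone. Comparisons of T1792del, T1792tg or rescue cells with wild-type or CD28ko-labelled cells therefore also differ in Cre. Within such a comparison an effect of Cre or of the mouse line cannot be told apart from one of the cluster.

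Every genotype had 4 naive and 4 stimulated libraries, except rescue with 3 of each. Total counts per naive library, in units of 1000000, were 21.1 to 24.6 in wild-type, 20.9 to 24.4 in CD28ko-labelled, 19.4 to 22.5 in T1792del, 20.1 to 25 in T1792tg and 21 to 22.1 in rescue. Stimulated libraries held, in the same unit, 22.6 to 26.5 in wild-type, 22.3 to 25.7 in CD28ko-labelled, 25.7 to 26.8 in T1792del, 25.8 to 26.9 in T1792tg and 25.4 to 28 in rescue. Levels are given as counts per 1000000 counts (CPM, mean ± SD over libraries), and changes as log2 fold changes ± SE from the edgeR quasi-likelihood fit. The sex of each mouse, read from Xist and Y-linked genes, was female for all CD28ko-labelled and rescue libraries, for 3 of 4 wild-type, 2 of 4 T1792del and 1 of 4 T1792tg libraries in both states.

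The engineered loci were read in every library first. Mir17hg, the host transcript of the miR-17~92 cluster (Entrez gene 75957, chromosome 14:115044390-115046728, GRCm38.p6), stood at 51.6 ± 7.25 CPM in naive wild-type, 54.4 ± 7.88 CPM in naive T1792del and 96.6 ± 10.1 CPM in naive T1792tg cells. At 24 h it was 20.7 ± 2.44 CPM in wild-type and 172 ± 11.8 CPM in T1792del cells, where the cluster is labelled as deleted. The annotated precursor Mir17, a member of the cluster, had 0.334 ± 0.0969 CPM in naive wild-type, 6.55 ± 0.9 CPM in naive T1792tg, 6.88 ± 1.84 CPM in naive rescue and 0.0641 ± 0.0766 CPM in naive T1792del cells. At 24 h Mir17 had 0.624 ± 0.231 CPM in T1792tg, 0.131 ± 0.0188 CPM in wild-type and no counts in T1792del cells. Gt(ROSA)26Sor, the transcript of the Rosa26 locus (chromosome 6:113067428-113077244), had 13.6 ± 1.4 CPM in naive T1792del against 0.215 ± 0.101 CPM in naive wild-type cells. In the genotypes with the Rosa26 transgene it had 0.676 ± 0.147 CPM in naive T1792tg and 0.464 ± 0.205 CPM in naive rescue cells. The T1792del label names no change at Rosa26, so it leaves that high level unexplained, and the cause was not tested. Cd28 (chromosome 1:60746388-60773359) had 737 ± 135 CPM in naive CD28ko-labelled and 825 ± 86.8 CPM in naive wild-type libraries, and 539 ± 40.4 against 342 ± 35.5 CPM at 24 h. The count per gene therefore does not check the CD28-/- label, since it includes reads from any part of the transcript that remains.

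**Figure D1:**
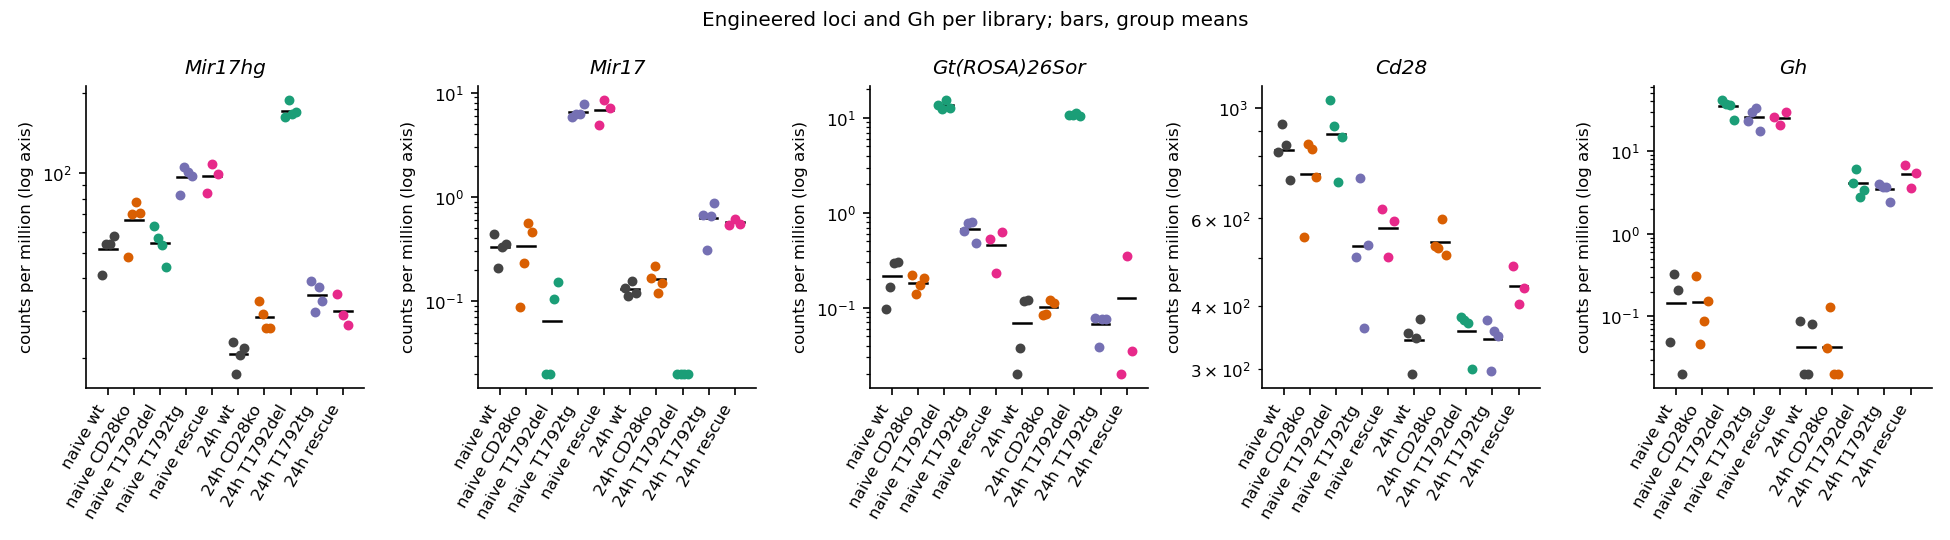
Level in CPM (log axis, counts of 0 drawn at the lower edge) of Mir17hg, Mir17, Gt(ROSA)26Sor, Cd28 and Gh in each library by group, with a bar at the group mean. Mir17hg at 24 h lay above every other group in T1792del, and the mean of Cd28 at 24 h was highest in the CD28ko-labelled libraries.

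Wild-type cells at 24 h were first compared with naive ones (4 against 4 libraries). No culture was unstimulated, so responses include effects of culture and interleukin-2. Il2, the gene of the T cell growth factor interleukin-2, rose from 0.221 ± 0.107 to 156 ± 23.7 CPM (log2 fold change 9.39 ± 0.30, adjusted p = 3.5e-25). Il3, another cytokine, had no counts in naive libraries and 8.93 ± 2.45 CPM at 24 h. It rose at least 263-fold against a floor of 3 counts. Bcat1, which starts the breakdown of branched-chain amino acids, rose from 1.38 ± 0.306 to 242 ± 7.01 CPM (log2 fold change 7.45 ± 0.15, adjusted p = 3.6e-30). Il2ra, the high-affinity interleukin-2 receptor chain, rose from 15.4 ± 1.38 to 641 ± 14.5 CPM (log2 fold change 5.38 ± 0.12, adjusted p = 1.6e-29). Pik3ip1, an inhibitor of the growth kinase PI3K, fell from 208 ± 16.2 to 3.7 ± 0.688 CPM (log2 fold change -5.82 ± 0.15, adjusted p = 7.2e-28).

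Growth and division genes rose together in these cells. Of the cell cycle list, 27 of 28 genes were higher and 0 lower (28 and 0 adjusted over the list alone). Mcm3 and E2f1, a replication helicase subunit and a G1/S transcription factor, changed by 3.77 ± 0.06 and 4.08 ± 0.10 on the log2 scale. All 20 ribosome biogenesis genes were higher (20 adjusted over the list alone). Amino acid and one-carbon genes had 17 of 19 higher and 1 lower (17 and 1 adjusted over the list alone), with Shmt1 at 5.00 ± 0.10. Glycolysis genes had 16 of 17 higher and 1 lower (16 and 1 adjusted over the list alone), with Hk2, the first enzyme of the pathway, at 5.83 ± 0.17. Cholesterol synthesis genes had 16 of 18 higher and 0 lower (16 and 0 adjusted over the list alone), with Idi1 at 3.67 ± 0.10. The activation surface markers had 14 of 18 higher and 2 lower (14 and 2 adjusted over the list alone), with Cd200 at 5.14 ± 0.11. The cytokine list had 14 of 17 higher and 1 lower (14 and 1 adjusted over the list alone). All 21 quiescence genes were lower (21 adjusted over the list alone), including Btg2, an antiproliferative gene, at -3.72 ± 0.09. The camera test of these lists gave adjusted p = 1.1e-16, and adjusted p = 0.026 with an estimated correlation for cell cycle. Ribosome biogenesis had adjusted p = 5.3e-15, and adjusted p = 0.004 with an estimated correlation, amino acid genes adjusted p = 1.2e-09, and adjusted p = 0.004 with an estimated correlation, surface markers adjusted p = 5.2e-05, and adjusted p = 0.013 with an estimated correlation, and quiescence genes adjusted p = 7.3e-17, and adjusted p = 0.004 with an estimated correlation. Glycolysis had adjusted p = 2.4e-06, and adjusted p = 0.19 with an estimated correlation, cholesterol genes adjusted p = 1.6e-05, and adjusted p = 0.19 with an estimated correlation, and cytokine genes adjusted p = 0.0096, and adjusted p = 0.31 with an estimated correlation.

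Other lists were mixed. Published miR-17~92 targets had 6 of 25 higher and 16 lower (6 and 16 adjusted over the list alone; adjusted p = 0.0039, and adjusted p = 0.19 with an estimated correlation), with Tgfbr2, a TGF-beta receptor, at -3.71 ± 0.09. PI3K brakes had 3 of 19 higher and 12 lower (3 and 11 adjusted over the list alone; adjusted p = 0.0037, and adjusted p = 0.19 with an estimated correlation). Interferon-stimulated genes had 6 of 21 higher and 14 lower (6 and 14 adjusted over the list alone). Calcineurin and NFAT genes had 4 of 14 higher and 8 lower (4 and 8 adjusted over the list alone). NF-kB genes had 7 of 16 higher and 8 lower (7 and 8 adjusted over the list alone). Activation transcription factors had 10 of 19 higher and 8 lower (10 and 8 adjusted over the list alone). Apoptosis genes had 8 of 16 higher and 8 lower (8 and 8 adjusted over the list alone). Helper lineage genes had 4 of 16 higher and 10 lower (4 and 10 adjusted over the list alone). Regulatory T cell markers had 3 of 10 higher and 5 lower (3 and 5 adjusted over the list alone). The camera adjusted p of these lists without a test beside them ran from 0.082 to 0.84. The activation transcription factors had a median of 0.24 and a mean of -0.02, and their test pointed down. Markers of other cells were lower after culture. They fell in 14 of 14 myeloid genes (14 adjusted over the list alone; adjusted p = 0.0025, and adjusted p = 0.3 with an estimated correlation) and in 14 of 15 B cell genes (14 adjusted over the list alone; adjusted p = 0.038, and adjusted p = 0.65 with an estimated correlation). They also fell in 8 of 10 NK and CD8 genes (8 adjusted over the list alone; adjusted p = 0.02, and adjusted p = 0.31 with an estimated correlation) and in 4 of 4 red cell genes (4 adjusted over the list alone; adjusted p = 0.44). Memory markers had 3 of 13 higher and 9 lower (3 and 9 adjusted over the list alone; adjusted p = 0.029, and adjusted p = 0.31 with an estimated correlation). Stress and dissociation genes had 2 of 12 higher and 9 lower (2 and 9 adjusted over the list alone; adjusted p = 0.0082, and adjusted p = 0.31 with an estimated correlation), with Fos, an immediate-early gene, at -5.86 ± 0.20. In all, 5637 genes were higher and 5990 lower of 13650 tested.

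The other genotypes were compared between the same states. CD28ko-labelled cells changed 11041 genes (5417 higher, 5624 lower), T1792del cells 11621 (5654 and 5967), T1792tg cells 11611 (5591 and 6020) and rescue cells 10874 (5298 and 5576). Il2 rose from 0.0554 ± 0.0418 to 6.96 ± 0.454 CPM in CD28ko-labelled (log2 fold change 6.79 ± 0.48, adjusted p = 3.1e-15), by 9.60 ± 0.32 on the log2 scale in T1792del, from 0.263 ± 0.134 to 215 ± 42.5 CPM in T1792tg (9.68 ± 0.29) and from 0.155 ± 0.196 to 14.5 ± 5.88 CPM in rescue cells (6.49 ± 0.42). Il2ra rose from 5.23 ± 0.594 to 546 ± 10.7 CPM in CD28ko-labelled (6.71 ± 0.13), by 4.97 ± 0.12 in T1792del, 5.53 ± 0.12 in T1792tg and 6.89 ± 0.15 in rescue cells on the log2 scale. Mcm3 rose by 3.39 ± 0.06, 3.94 ± 0.06, 3.71 ± 0.06 and 3.57 ± 0.07 in the same order. Ribosome biogenesis genes were all higher in each genotype (20, 20, 20 and 20 of 20; as many adjusted over the list alone; camera adjusted p = 0.0048, 0.0043, 0.001 and 0.0011 with an estimated correlation). Quiescence genes fell in 20, 21, 20 and 19 of 21 members (as many adjusted over the list alone). Myeloid markers fell in 14, 14, 14 and 14 of 14 (as many adjusted over the list alone).

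Naive cells were compared next. Naive CD28ko-labelled cells had fewer transcripts of regulatory T cells, the suppressive lineage that needs CD28 to form. Foxp3, its lineage factor, stood at 4.63 ± 0.832 CPM against 21.7 ± 1.64 CPM in wild-type (log2 fold change -2.23 ± 0.20, adjusted p = 1.1e-09, 4 against 4 libraries). Lrrc32, which presents latent TGF-beta on those cells, fell from 20.4 ± 1.41 to 2.65 ± 0.471 CPM (log2 fold change -2.94 ± 0.18, adjusted p = 3.1e-14). Of the regulatory T cell markers, 1 of 10 genes were higher and 5 lower (1 and 6 adjusted over the list alone; adjusted p = 1.9e-08, and adjusted p = 5.3e-05 with an estimated correlation). Il2ra fell (-1.56 ± 0.12), and so did Lif (-2.23 ± 0.20) and Myc (-0.83 ± 0.09), while Pdcd1, the inhibitory receptor PD-1, rose (1.48 ± 0.18). NF-kB genes had 0 of 16 higher and 11 lower (0 and 11 adjusted over the list alone; adjusted p = 1.9e-08, and adjusted p = 0.013 with an estimated correlation), with Nfkbid at -1.24 ± 0.13. Activation transcription factors had 0 of 19 higher and 8 lower (0 and 8 adjusted over the list alone; adjusted p = 1.4e-08, and adjusted p = 0.0066 with an estimated correlation), with Egr2 at -1.14 ± 0.15. Interferon-stimulated genes had 11 of 21 higher and 0 lower (12 and 0 adjusted over the list alone; adjusted p = 2.2e-06, and adjusted p = 0.31 with an estimated correlation), with Ifit1 at 1.65 ± 0.24. Beside these, stress genes had 0 of 12 higher and 7 lower (1 and 8 adjusted over the list alone; adjusted p = 1.4e-04, and adjusted p = 0.22 with an estimated correlation), with Fosb at -1.51 ± 0.19. Myeloid markers had 0 of 14 higher and 5 lower (0 and 7 adjusted over the list alone; adjusted p = 0.0029, and adjusted p = 0.31 with an estimated correlation). In all, 1013 genes were higher and 1002 lower. The count of 2015 was 1307 without wild-type 2, 1331 without wild-type 3, 1170 without CD28ko-labelled 4 and 956 when the compared groups were fitted alone.

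Naive T1792del cells differed less from wild-type. Gt(ROSA)26Sor rose from 0.215 ± 0.101 to 13.6 ± 1.4 CPM (log2 fold change 5.95 ± 0.33, adjusted p = 2.3e-15). Gh, the growth hormone gene, read 34.8 ± 7.74 CPM against 0.147 ± 0.151 CPM (log2 fold change 7.74 ± 0.40, adjusted p = 4.4e-16, 4 against 4 libraries). Rcan3, a calcineurin inhibitor and published target of the cluster, rose (log2 fold change 0.48 ± 0.08, adjusted p = 8.7e-05), as did Bcl2, a survival gene (0.59 ± 0.08), and Nfkbia, the inhibitor of NF-kB (0.49 ± 0.06). Egr2 fell (-1.14 ± 0.15), and activation transcription factors had 0 of 19 higher and 5 lower (0 and 5 adjusted over the list alone; adjusted p = 0.0053, and 0.37 with an estimated correlation). Published targets had 3 of 25 higher and 0 lower (3 and 0 adjusted over the list alone; adjusted p = 0.44). Cholesterol genes had 3 of 18 higher and 0 lower (6 and 0 adjusted over the list alone; adjusted p = 3.6e-05, and 0.37 with an estimated correlation). Myeloid markers had 7 of 14 higher and 0 lower (8 and 0 adjusted over the list alone; adjusted p = 5.8e-07, and 0.32 with an estimated correlation), with Csf1r, a macrophage receptor, at 1.46 ± 0.23. Stress genes had 0 of 12 higher and 5 lower (1 and 7 adjusted over the list alone; adjusted p = 0.0023, and 0.37 with an estimated correlation). In all, 377 genes were higher and 331 lower. The count of 708 was 469 without wild-type 3, 439 without T1792del 3 and 397 with female libraries alone.

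Naive T1792tg cells carried the transgene's mark and a broad change. The precursors Mir17 and Mir18 rose by 4.29 ± 0.34 and 4.11 ± 0.32 on the log2 scale, and Mir17hg rose from 51.6 ± 7.25 to 96.6 ± 10.1 CPM (log2 fold change 0.90 ± 0.13, adjusted p = 2.5e-06, 4 against 4 libraries). Adgrg5, an adhesion receptor, rose from 7.29 ± 2.35 to 86.2 ± 21.8 CPM (log2 fold change 3.55 ± 0.22, adjusted p = 6.6e-14). Rcan3 fell from 73.1 ± 2.75 to 39.8 ± 3.2 CPM (log2 fold change -0.88 ± 0.08, adjusted p = 3.4e-10), as did Bcl2 (-0.65 ± 0.08) and Fasl, a death ligand (-1.40 ± 0.14). Of the published targets, 1 of 25 genes were higher and 8 lower (1 and 10 adjusted over the list alone; adjusted p = 0.0049, and adjusted p = 0.3 with an estimated correlation). Quiescence genes had 0 of 21 higher and 10 lower (1 and 13 adjusted over the list alone; adjusted p = 3.5e-06, and adjusted p = 0.23 with an estimated correlation), with the naive T cell factor Lef1 at -0.63 ± 0.07. Ribosome biogenesis genes had 0 of 20 higher and 12 lower (0 and 13 adjusted over the list alone; adjusted p = 3.5e-06, and adjusted p = 0.14 with an estimated correlation). Interferon-stimulated genes had 12 of 21 higher and 0 lower (12 and 0 adjusted over the list alone; adjusted p = 1.4e-05, and adjusted p = 0.45 with an estimated correlation). Memory markers had 7 of 13 higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.013, and adjusted p = 0.39 with an estimated correlation). Eomes, a factor of memory and effector cells, rose by 1.45 ± 0.19 and Pdcd1 by 1.41 ± 0.18. Regulatory T cell markers had 5 of 10 higher and 0 lower (6 and 0 adjusted over the list alone; adjusted p = 0.0028, and adjusted p = 0.051 with an estimated correlation), with Ikzf2 at 0.98 ± 0.15. No B cell marker passed the test in either direction, while that list as a whole tested higher (adjusted p = 0.015, and adjusted p = 0.79 with an estimated correlation). In all, 1439 genes were higher and 1719 lower. The count of 3158 was 1913 with the compared groups alone and 518 with female libraries alone, which left a single T1792tg library, assumed to vary like the other groups.

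The transgene on the CD28-/- background was read in naive rescue against naive CD28ko-labelled cells (3 against 4 libraries). Mir17 read 6.88 ± 1.84 CPM against 0.336 ± 0.216 CPM (log2 fold change 4.34 ± 0.35, adjusted p = 2.5e-10). Adgrg5 rose from 6.79 ± 1.7 to 65.8 ± 14.7 CPM (3.27 ± 0.23). H2-Q6, a class I antigen gene whose reads near-identical copies share, rose by 2.12 ± 0.17. Rcan3 fell from 64.5 ± 2.77 to 43.3 ± 6.11 CPM (log2 fold change -0.57 ± 0.08, adjusted p = 1.0e-05), and Fasl (-1.17 ± 0.15), Bcl2 (-0.55 ± 0.09) and Lef1 (-0.46 ± 0.08) fell too. Of the published targets, 2 of 25 genes were higher and 8 lower (2 and 11 adjusted over the list alone; adjusted p = 0.041, and adjusted p = 0.6 with an estimated correlation). Quiescence genes had 0 of 21 higher and 9 lower (0 and 12 adjusted over the list alone; adjusted p = 4.2e-04, and adjusted p = 0.6 with an estimated correlation). Ribosome biogenesis genes had 0 of 20 higher and 9 lower (0 and 12 adjusted over the list alone; adjusted p = 3.5e-05, and adjusted p = 0.4 with an estimated correlation). Foxp3 read 5.65 ± 0.352 CPM in naive rescue cells. In all, 1070 genes were higher and 1218 lower, and 1353 of them moved as in naive T1792tg against wild-type, where independent lists of those sizes would share 266, against 4 that moved oppositely. Both comparisons also differ in Cre. The count of 2288 was 802 with the compared groups alone.

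The comparison of stimulated CD28ko-labelled with stimulated wild-type cells asked what the loss of CD28 signals did at 24 h (4 against 4 libraries). Il2 fell from 156 ± 23.7 to 6.96 ± 0.454 CPM (log2 fold change -4.48 ± 0.20, adjusted p = 8.6e-19). Il1a, an inflammatory cytokine gene, fell from 9 ± 2.05 to 0.0918 ± 0.0408 CPM (-6.54 ± 0.39). Tbx21, the factor that drives the T helper 1 lineage, fell from 117 ± 18.3 to 7.46 ± 1.85 CPM (log2 fold change -3.97 ± 0.26, adjusted p = 1.0e-14), and Lif, a cytokine of the interleukin-6 family, by 2.96 ± 0.16. S1pr1, the receptor that lets resting T cells leave lymph nodes, rose from 5.05 ± 1.38 to 40.8 ± 9.74 CPM (log2 fold change 3.01 ± 0.19, adjusted p = 1.0e-14), as did Pik3ip1 (2.63 ± 0.14), the diacylglycerol kinase gene Dgka (1.54 ± 0.07), and Klf2 (2.43 ± 0.18), a factor of resting T cells. Of the quiescence list, 19 of 21 genes were higher and 0 lower (20 and 1 adjusted over the list alone; adjusted p = 2.3e-14, and adjusted p = 0.03 with an estimated correlation). Of the PI3K brakes, 10 of 19 genes were higher and 5 lower (10 and 5 adjusted over the list alone; adjusted p = 6.7e-06, and adjusted p = 0.039 with an estimated correlation). Of the cytokine list, 2 of 17 genes were higher and 13 lower (2 and 13 adjusted over the list alone; adjusted p = 9.6e-08, and adjusted p = 0.039 with an estimated correlation). Of the surface markers, 2 of 18 genes were higher and 12 lower (2 and 12 adjusted over the list alone; adjusted p = 5.2e-04, and adjusted p = 0.039 with an estimated correlation), with Cd44 at -1.10 ± 0.12.

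Growth programmes were lower in the same comparison. Amino acid genes had 0 of 19 higher and 15 lower (0 and 15 adjusted over the list alone; adjusted p = 3.4e-06, and adjusted p = 0.039 with an estimated correlation), with the one-carbon enzyme Mthfd2 at -1.26 ± 0.07. Cell cycle genes had 1 of 28 higher and 22 lower (1 and 22 adjusted over the list alone; adjusted p = 2.7e-07, and adjusted p = 0.2 with an estimated correlation), with Ccnd3 at -0.85 ± 0.06. Ribosome biogenesis genes had 0 of 20 higher and 17 lower (0 and 18 adjusted over the list alone; adjusted p = 1.1e-05, and adjusted p = 0.077 with an estimated correlation). Glycolysis genes had 1 of 17 higher and 12 lower (1 and 13 adjusted over the list alone; adjusted p = 6.5e-05, and adjusted p = 0.33 with an estimated correlation), with Ldha, lactate dehydrogenase, at -0.96 ± 0.09. Cholesterol genes had 1 of 18 higher and 10 lower (1 and 12 adjusted over the list alone; adjusted p = 0.024, and adjusted p = 0.62 with an estimated correlation). Bcl2l11, which encodes the death factor BIM and is a published target, rose by 1.33 ± 0.10, while the survival gene Bcl2l1 fell by 1.22 ± 0.08 on the log2 scale. The published targets as a list had 10 of 25 higher and 7 lower (10 and 7 adjusted over the list alone; adjusted p = 0.1). NF-kB genes had 3 of 16 higher and 6 lower (3 and 6 adjusted over the list alone; adjusted p = 0.39). Calcineurin and NFAT genes had 6 of 14 higher and 2 lower (6 and 2 adjusted over the list alone; adjusted p = 0.11). B cell markers had 5 of 15 higher and 0 lower (5 and 0 adjusted over the list alone; adjusted p = 0.11). NK and CD8 markers had 2 of 10 higher and 6 lower (2 and 6 adjusted over the list alone; adjusted p = 0.52). In all, 3236 genes were higher and 3793 lower, 1435 of them by at least 2-fold.

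The loss of the cluster was read in stimulated T1792del against wild-type cells (4 against 4 libraries). Mir17hg rose from 20.7 ± 2.44 to 172 ± 11.8 CPM (log2 fold change 3.06 ± 0.14, adjusted p = 4.8e-18) and Gt(ROSA)26Sor by 7.16 ± 0.38 on the log2 scale. Ifng, the T helper 1 cytokine, fell from 12.1 ± 5.95 to 2.48 ± 1.22 CPM (log2 fold change -2.28 ± 0.39, adjusted p = 8.0e-05) and Tbx21 from 117 ± 18.3 to 25 ± 8.4 CPM (log2 fold change -2.22 ± 0.23, adjusted p = 1.9e-08), and the interferon-induced GTPase genes Iigp1 and Irgm1 changed by -2.76 ± 0.25 and -1.64 ± 0.16. Of the interferon-stimulated genes, 0 of 21 genes were higher and 10 lower (0 and 10 adjusted over the list alone; adjusted p = 9.9e-15, and adjusted p = 0.16 with an estimated correlation). Of the cytokine list, 2 of 17 genes were higher and 7 lower (2 and 8 adjusted over the list alone; adjusted p = 2.1e-04, and adjusted p = 0.26 with an estimated correlation), with Lta at -1.06 ± 0.12 and Lif at -1.11 ± 0.15. Il2ra fell by 0.73 ± 0.10 on the log2 scale. Of the published targets, 9 of 25 genes were higher and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 5.2e-06, and adjusted p = 0.13 with an estimated correlation), among them Rcan3 (0.67 ± 0.08), Tgfbr2 (0.64 ± 0.08) and Bcl2l11 (0.60 ± 0.10). Cholesterol genes had 9 of 18 higher and 0 lower (13 and 0 adjusted over the list alone; adjusted p = 6.7e-07, and adjusted p = 0.26 with an estimated correlation). Glycolysis genes had 5 of 17 higher and 0 lower (5 and 0 adjusted over the list alone; adjusted p = 0.0081, and adjusted p = 0.65 with an estimated correlation). Red cell markers, whose reads near-identical copies share, had 1 of 4 higher and 0 lower (2 and 0 adjusted over the list alone; adjusted p = 0.12). Among them the globin gene Hba-a2 was higher (log2 fold change 2.85 ± 0.95, adjusted p = 0.0346), from a wild-type mean of 3.78 ± 0.58 CPM, and read 57.4 and 35.6 CPM in T1792del 1 and 2 but 8.38 and 7.45 CPM in 3 and 4. That call ended without T1792del 1 (2.19) or 2 (2.70) and without wild-type 1 (2.91), 2 (2.77), 3 (2.92) or 4 (2.82). NK and CD8 markers had 1 of 10 higher and 0 lower (1 and 0 adjusted over the list alone; adjusted p = 0.4), with Gzma, a granzyme of cytotoxic cells, at 1.28 ± 0.42, a call that ended without wild-type 1 (1.26), 3 (1.12) or 4 (1.32) and without T1792del 1 (1.29), 2 (1.2) or 3 (1.02). In all, 1060 genes were higher and 1156 lower. The count of 2216 was 1388 without T1792del 1 and 672 with female libraries alone. P4ha2, Slc16a3 and Slc2a3, genes of hypoxia and glucose metabolism, read highest in T1792del 2, at 20.4, 159 and 255 CPM against at most 2.96, 51.5 and 47.9 CPM in the other 3 libraries.

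The gain of the cluster was read in stimulated T1792tg against wild-type cells (4 against 4 libraries). Ifng rose from 12.1 ± 5.95 to 65.5 ± 25.1 CPM (log2 fold change 2.43 ± 0.35, adjusted p = 7.0e-06). Cxcr3, a homing receptor of T helper 1 cells, rose from 2.17 ± 0.412 to 9.28 ± 1.18 CPM (log2 fold change 2.09 ± 0.28, adjusted p = 2.3e-06). Runx2, a transcription factor, rose by 2.42 ± 0.23, Cd44, an adhesion receptor of activated cells, by 1.36 ± 0.12 and Eomes by 1.72 ± 0.19. Tbc1d4, a regulator of glucose transporter traffic, fell by 1.26 ± 0.10 and Dgka by 0.62 ± 0.07 on the log2 scale. Of the cytokine list, 9 of 17 genes were higher and 0 lower (10 and 0 adjusted over the list alone; adjusted p = 7.1e-09, and adjusted p = 0.028 with an estimated correlation), with Lta at 0.97 ± 0.12. Helper lineage genes had 6 of 16 higher and 0 lower (8 and 2 adjusted over the list alone; adjusted p = 3.1e-05, and adjusted p = 0.028 with an estimated correlation), with Il12rb2 at 1.57 ± 0.19. Memory markers had 6 of 13 higher and 0 lower (6 and 0 adjusted over the list alone; adjusted p = 7.1e-09, and adjusted p = 0.027 with an estimated correlation). Interferon-stimulated genes had 6 of 21 higher and 1 lower (13 and 1 adjusted over the list alone; adjusted p = 9.1e-06, and adjusted p = 0.37 with an estimated correlation). Of the published targets, 1 of 25 genes were higher and 4 lower (1 and 5 adjusted over the list alone; adjusted p = 0.46), with a median of 0.02, a mean of -0.02 and a test pointing down. Among them were Rcan3 at -0.49 ± 0.08 and Btg2 at -0.49 ± 0.08. NK and CD8 markers had 4 of 10 higher and 0 lower (5 and 0 adjusted over the list alone; adjusted p = 0.0056, and adjusted p = 0.37 with an estimated correlation). Stress and dissociation genes had 3 of 12 higher and 0 lower (3 and 0 adjusted over the list alone; adjusted p = 0.027, and adjusted p = 0.49 with an estimated correlation), with the immediate-early genes Jun at 1.10 ± 0.14 and Fosb at 2.01 ± 0.32. In all, 833 genes were higher and 880 lower. The count of 1713 was 1092 without wild-type 1, 1092 without T1792tg 3, 962 without T1792tg 4, 2631 with the compared groups alone and 221 with female libraries alone.

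Whether the transgene changed what CD28ko-labelled cells did was asked in stimulated rescue against stimulated CD28ko-labelled cells (3 against 4 libraries). Tbx21 rose from 7.46 ± 1.85 to 85.2 ± 30.6 CPM (log2 fold change 3.52 ± 0.26, adjusted p = 1.0e-11), Il12rb2, a receptor chain for the T helper 1 cytokine interleukin-12, rose from 2.62 ± 0.542 to 25.1 ± 7.44 CPM (log2 fold change 3.26 ± 0.23, adjusted p = 6.4e-12) and Ifng from 1.76 ± 0.21 to 11.4 ± 4.69 CPM (log2 fold change 2.69 ± 0.43, adjusted p = 1.8e-05). Lif rose by 2.26 ± 0.16, Cd44 by 1.43 ± 0.13 and the interferon-induced gene Iigp1 by 3.07 ± 0.26. S1pr1 fell from 40.8 ± 9.74 to 16.3 ± 4.62 CPM (log2 fold change -1.32 ± 0.19, adjusted p = 4.5e-06), as did Rcan3 (-0.72 ± 0.08), Dgka (-0.62 ± 0.08) and Pik3ip1 (-0.85 ± 0.14). Of the cytokine list, 12 of 17 genes were higher and 0 lower (14 and 0 adjusted over the list alone; adjusted p = 2.3e-12, and adjusted p = 0.023 with an estimated correlation). Of the quiescence list, 0 of 21 genes were higher and 16 lower (0 and 17 adjusted over the list alone; adjusted p = 2.3e-12, and adjusted p = 0.032 with an estimated correlation). Interferon-stimulated genes had 13 of 21 higher and 0 lower (15 and 0 adjusted over the list alone; adjusted p = 6.4e-18, and adjusted p = 0.058 with an estimated correlation). Cell cycle genes had 13 of 28 higher and 0 lower (17 and 0 adjusted over the list alone; adjusted p = 1.9e-07, and adjusted p = 0.17 with an estimated correlation), with Cdc25a at 0.62 ± 0.07. Amino acid genes had 7 of 19 higher and 0 lower (9 and 0 adjusted over the list alone; adjusted p = 1.2e-04, and adjusted p = 0.077 with an estimated correlation), with Mthfd2 at 0.57 ± 0.07. Of the published targets, 3 of 25 genes were higher and 9 lower (4 and 9 adjusted over the list alone; adjusted p = 0.02, and adjusted p = 0.27 with an estimated correlation). In all, 1300 genes were higher and 1210 lower. The count of 2510 was 1300 without rescue 2, 1595 without rescue 3 and 3851 with the compared groups alone.

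**Figure D2:**
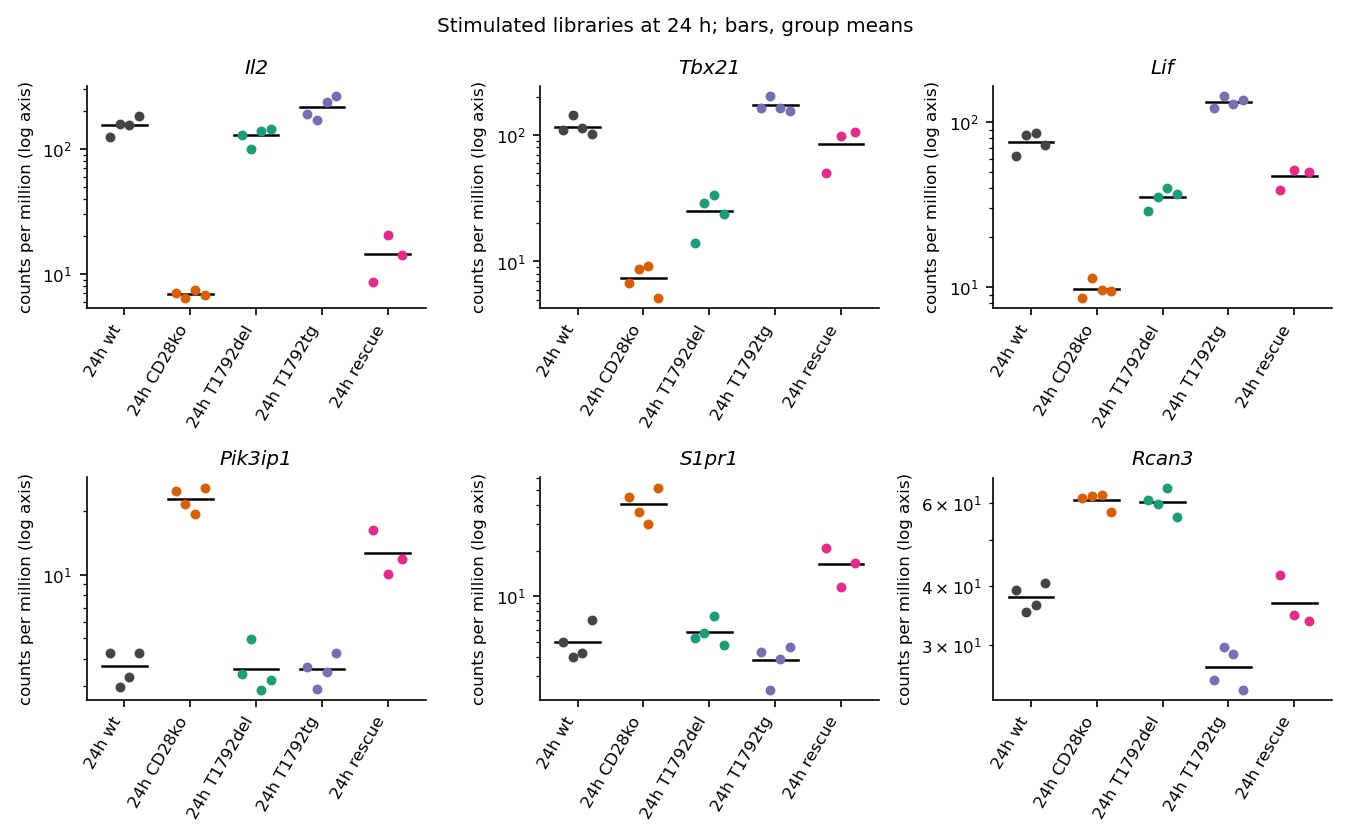
Level in CPM (log axis) of Il2, Tbx21, Lif, Pik3ip1, S1pr1 and Rcan3 in each stimulated library by genotype, with a bar at the group mean. Il2 fell from 156 ± 23.7 to 6.96 ± 0.454 CPM in CD28ko-labelled against wild-type libraries, and Tbx21 rose from 7.46 ± 1.85 to 85.2 ± 30.6 CPM in rescue against CD28ko-labelled libraries.

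What distance from wild-type remained was read in stimulated rescue against wild-type cells (3 against 4 libraries). Il2 was lower, from 156 ± 23.7 to 14.5 ± 5.88 CPM (log2 fold change -3.43 ± 0.20, adjusted p = 7.5e-15), and so were Il1a (-3.16 ± 0.30) and the surface marker Cd200 (-1.21 ± 0.10). Pik3ip1 (1.79 ± 0.16), S1pr1 (1.69 ± 0.20) and Dgka (0.92 ± 0.08) stayed higher. Eomes (2.11 ± 0.20) and Crtam, an adhesion molecule of cytotoxic T cells (log2 fold change 2.73 ± 0.12, adjusted p = 1.1e-17), were higher than in wild-type cells. Of the quiescence list, 14 of 21 genes were higher and 1 lower (14 and 1 adjusted over the list alone; adjusted p = 8.3e-07, and adjusted p = 0.22 with an estimated correlation). PI3K brakes had 10 of 19 higher and 4 lower (11 and 5 adjusted over the list alone; adjusted p = 3.1e-06, and adjusted p = 0.14 with an estimated correlation). Glycolysis genes had 0 of 17 higher and 11 lower (0 and 13 adjusted over the list alone; adjusted p = 1.9e-04, and adjusted p = 0.36 with an estimated correlation). Amino acid genes had 0 of 19 higher and 11 lower (1 and 12 adjusted over the list alone; adjusted p = 0.0019, and adjusted p = 0.22 with an estimated correlation). Interferon-stimulated genes had 13 of 21 higher and 1 lower (14 and 1 adjusted over the list alone; adjusted p = 1.4e-06, and adjusted p = 0.33 with an estimated correlation), with Irf7 at 2.44 ± 0.35. NK and CD8 markers had 2 of 10 higher and 2 lower (2 and 2 adjusted over the list alone; adjusted p = 0.77). Stress genes had 2 of 12 higher and 1 lower (2 and 1 adjusted over the list alone; adjusted p = 0.69). In all, 2372 genes were higher and 2422 lower.

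Of the 7029 genes that differed between CD28ko-labelled and wild-type cells at 24 h, 1986 moved the opposite way in rescue against CD28ko-labelled cells and 81 the same way. Both comparisons use the CD28ko-labelled libraries, which alone gives a negative covariance. Independent lists of those sizes would give 648 opposite and 644 same. With the CD28ko-labelled libraries divided so that each comparison used its own, a mean of 1133 genes (1014 to 1226 over 6 divisions) moved oppositely and 41.8 the same way, with 321 opposite for independent lists of those sizes. The covariance of the log2 fold changes across genes was -0.257, against -0.083 (-0.089 to -0.076) in 20 simulated sets in which none of the 3 groups differed. In 20 sets that kept the CD28ko-labelled difference and had no rescue effect it was -0.082 (-0.105 to -0.068). Genes are not independent replicates. Of the opposite genes, 958 still differed from wild-type. By list, 15 of 19 changed quiescence genes, 9 of 15 cytokine genes, 13 of 23 cell cycle genes, 5 of 15 PI3K brakes and 2 of 13 glycolysis genes moved oppositely. Rescue and T1792tg share no library, and 829 genes moved the same way in T1792tg against wild-type and rescue against CD28ko-labelled cells, with 157 for independent lists and 20 opposite. Both comparisons also differ in Cre. So does stimulated T1792del against wild-type, yet 660 genes moved there opposite to rescue against CD28ko-labelled cells and 108 the same way. Independent lists would give 204 and 203.

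The stimulation responses themselves were then compared by interaction. In CD28ko-labelled cells the response of Tbx21 was lower (interaction log2 fold change -4.11 ± 0.41, adjusted p = 8.6e-10; 4 libraries in each of the 4 groups) and so was that of Sh2d1a, an adaptor of surface receptors (-3.47 ± 0.16). Nt5e, the adenosine-producing enzyme CD73, and Gucy1a1, a guanylate cyclase subunit, had higher responses (log2 fold change 3.69 ± 0.25, adjusted p = 1.8e-13, and 3.59 ± 0.25). Il2ra had a higher response (1.33 ± 0.15) from its lower naive level. Of the quiescence list, 20 of 21 genes were higher and 0 lower (20 and 0 adjusted over the list alone; adjusted p = 1.2e-15, and adjusted p = 0.018 with an estimated correlation), with Pik3ip1 at 2.76 ± 0.18 and Klf2 at 2.84 ± 0.24. Cell cycle genes had 0 of 28 higher and 22 lower (0 and 22 adjusted over the list alone; adjusted p = 5.0e-08, and adjusted p = 0.18 with an estimated correlation), with Ccne2 at -2.40 ± 0.22. Amino acid genes had 0 of 19 higher and 10 lower (0 and 10 adjusted over the list alone; adjusted p = 8.4e-04, and adjusted p = 0.16 with an estimated correlation). PI3K brakes had 10 of 19 higher and 3 lower (10 and 3 adjusted over the list alone; adjusted p = 1.1e-05, and adjusted p = 0.095 with an estimated correlation). Stress genes had 4 of 12 higher and 1 lower (4 and 1 adjusted over the list alone; adjusted p = 0.17), with Fosb at 4.14 ± 0.36. In all, 2846 genes had a higher and 3059 a lower response than in wild-type.

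T1792del cells differed from wild-type in the response of fewer genes, 430 higher and 403 lower (4 libraries in each of the 4 groups). Mir17hg had a higher response (log2 fold change 2.98 ± 0.18, adjusted p = 1.3e-13). Ly6a and Ly6c1, surface antigens that interferon induces, had lower responses (log2 fold change -2.23 ± 0.33, adjusted p = 6.9e-05, and -2.45 ± 0.31), as did Irgm1 (-1.53 ± 0.22) and Irf8 (-1.72 ± 0.29). Of the interferon-stimulated genes, 0 of 21 genes were higher and 11 lower (0 and 14 adjusted over the list alone; adjusted p = 1.3e-16, and adjusted p = 0.23 with an estimated correlation). Published targets had 4 of 25 higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.0032, and adjusted p = 0.42 with an estimated correlation). Cytokine genes had 0 of 17 higher and 4 lower (1 and 5 adjusted over the list alone; adjusted p = 0.012, and adjusted p = 0.52 with an estimated correlation). The total of 833 was 467 without naive wild-type 3, 443 without stimulated T1792del 1, 141 with female libraries alone and 1251 with DESeq2.

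In T1792tg cells 1173 genes had a higher and 1012 a lower response than in wild-type (4 libraries in each of the 4 groups). Plaur, the urokinase receptor, and Myo10, a myosin of cell protrusions, had higher responses (log2 fold change 1.90 ± 0.25, adjusted p = 5.3e-06, and 1.82 ± 0.18), and so did Fasl (1.65 ± 0.20) and Dusp5 (0.91 ± 0.12). Nrn1, neuritin, and Pdcd1 had lower ones (-1.97 ± 0.25 and -1.57 ± 0.23). Ribosome biogenesis genes had 13 of 20 higher and 0 lower (13 and 0 adjusted over the list alone; adjusted p = 6.6e-09, and adjusted p = 0.058 with an estimated correlation), with Nop58 at 0.51 ± 0.09. Quiescence genes had 10 of 21 higher and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 2.8e-04, and adjusted p = 0.41 with an estimated correlation), with Il7r, the interleukin-7 receptor, at 1.65 ± 0.26. Activation transcription factors had 8 of 19 higher and 2 lower (9 and 2 adjusted over the list alone; adjusted p = 0.0026, and adjusted p = 0.25 with an estimated correlation). The total of 2185 was 69 with female libraries alone.

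Rescue against CD28ko-labelled responses differed in 950 genes that were higher and 797 that were lower (3 and 4 libraries per group). Tbx21 had a higher response (log2 fold change 3.0 ± 0.42, adjusted p = 1.5e-05), with Il12rb2 (2.56 ± 0.35), Irgm1 (1.99 ± 0.24) and Cd44 (1.48 ± 0.19). Pdk2, a kinase that restrains pyruvate oxidation, and Pglyrp1 had lower responses (log2 fold change -1.83 ± 0.25, adjusted p = 1.2e-05, and -1.86 ± 0.27). Ribosome biogenesis genes had 13 of 20 higher and 0 lower (16 and 0 adjusted over the list alone; adjusted p = 8.6e-12, and adjusted p = 0.018 with an estimated correlation). Amino acid genes had 7 of 19 higher and 0 lower (9 and 0 adjusted over the list alone; adjusted p = 3.1e-05, and adjusted p = 0.083 with an estimated correlation), with Mthfd1 at 0.64 ± 0.09. Interferon-stimulated genes had 11 of 21 higher and 0 lower (14 and 0 adjusted over the list alone; adjusted p = 8.4e-12, and adjusted p = 0.21 with an estimated correlation). The total of 1747 was 1000 without stimulated rescue 2 and 1144 without stimulated rescue 3.

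Whether the transgene acted more without CD28 at 24 h was asked by the difference between its effects on the wild-type and the CD28-/- background (4 libraries per group, 3 for rescue). Tbx21 rose more on the CD28-/- background (log2 fold change 2.96 ± 0.34, adjusted p = 7.4e-07), as did Tbkbp1, an adaptor of the TBK1 kinase (2.56 ± 0.29), Ifitm3, an interferon-induced membrane protein (2.05 ± 0.23), Lif (1.46 ± 0.22) and Irgm1 (1.46 ± 0.22). Il7r (log2 fold change -1.71 ± 0.28, adjusted p = 3.9e-04), Ahnak (-1.68 ± 0.26) and Tcf7, a factor of naive and memory T cells (-0.58 ± 0.10), moved down relative to the effect on the wild-type background. Of the quiescence list, 0 of 21 genes were higher and 5 lower (0 and 11 adjusted over the list alone; adjusted p = 3.8e-16, and adjusted p = 0.016 with an estimated correlation). Cell cycle genes had 8 of 28 higher and 0 lower (17 and 0 adjusted over the list alone; adjusted p = 1.7e-13, and adjusted p = 0.13 with an estimated correlation). Interferon-stimulated genes had 6 of 21 higher and 0 lower (8 and 0 adjusted over the list alone; adjusted p = 9.0e-08, and adjusted p = 0.4 with an estimated correlation). In all, 181 genes were more positive and 107 more negative on the CD28-/- background. The total of 288 was 181 without wild-type 1, 178 without wild-type 2, 172 without T1792tg 3, 172 without T1792tg 4, and 447, 119 and 132 without rescue 1, rescue 2 and rescue 3. It was 30 with female libraries alone, 522 with DESeq2, 929 with the compared groups alone and 487 without naive CD28ko-labelled 1 and naive rescue 2.

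**Figure D3:**
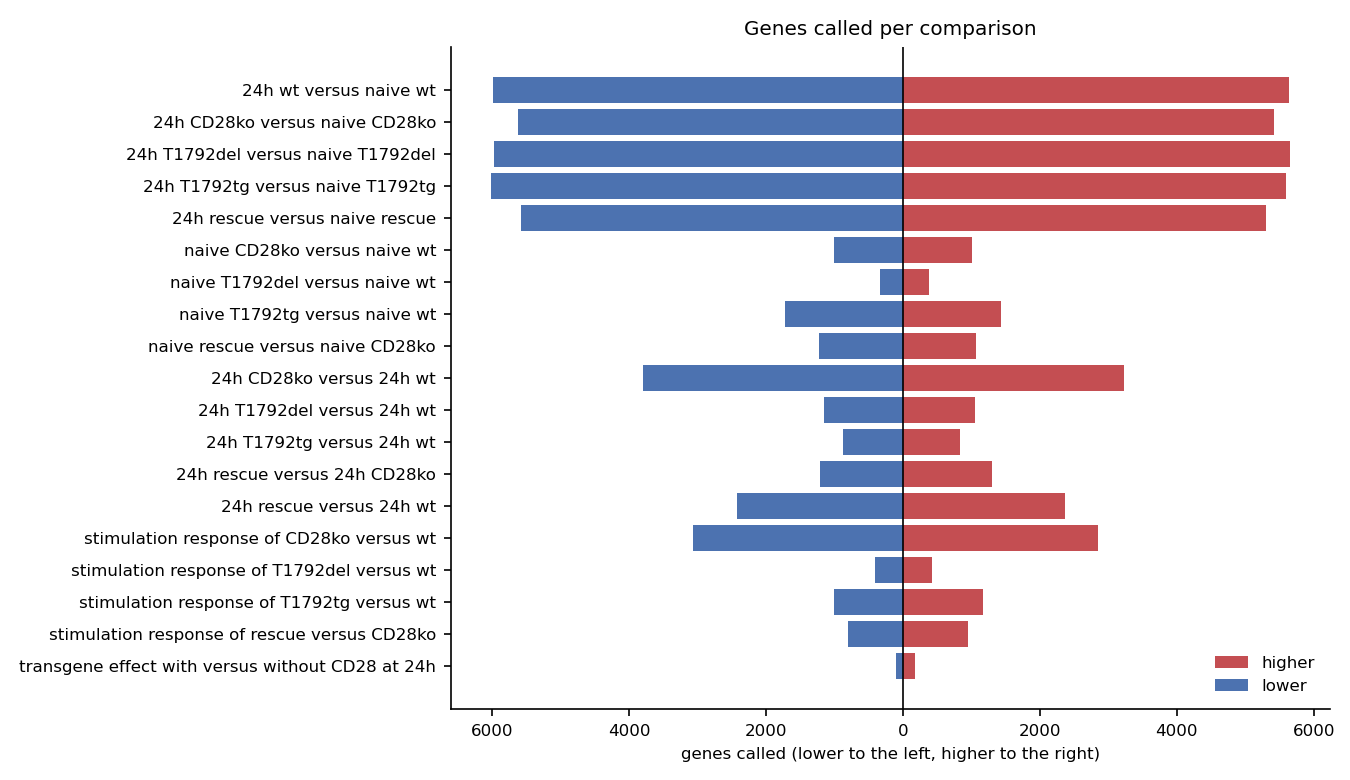
Number of genes with a Benjamini-Hochberg adjusted p under 0.05 in each of the 19 comparisons, with bars to the right for higher and to the left for lower genes, starting at 0. Stimulation changed between 10874 and 11627 genes, and the comparisons between genotypes between 288 and 7029.

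Genes with sites for the cluster's seeds in their 3' untranslated region were compared with genes without, since the cluster's microRNAs lower messages that carry such sites. Among 12659 tested genes with an annotated region, 4151 had a site. In stimulated T1792del against wild-type cells the median log2 fold change of genes with a site lay 0.092 above that of genes without (574 genes with a site were higher and 231 lower; camera adjusted p = 2.4e-04, and adjusted p = 0.16 with an estimated correlation). In naive T1792tg against wild-type cells the difference was -0.102 (312 higher, 819 lower; camera adjusted p = 8.1e-04, and adjusted p = 0.16 with an estimated correlation), and in naive rescue against CD28ko-labelled cells -0.074 (245 higher, 573 lower; camera adjusted p = 0.0042, and adjusted p = 0.18 with an estimated correlation). With 3222 genes with and 3222 without a site, matched on length and expression, the median difference was 0.065 (adjusted p = 0.016, and 0.081 with an estimated correlation) in stimulated T1792del cells. In naive T1792tg it was -0.072 (adjusted p = 0.02, and 0.081 with an estimated correlation) and in naive rescue cells -0.058 (adjusted p = 0.02, and 0.081 with an estimated correlation). In these matched classes no shift passed in stimulated rescue against CD28ko-labelled cells at -0.055 (adjusted p = 0.056), stimulated T1792tg at -0.022 (adjusted p = 0.27) or naive T1792del against wild-type cells at 0.024 (adjusted p = 0.32). Shifts of similar or larger size lay where the cluster was not engineered. The median difference was -0.302 in wild-type stimulation (1531 higher, 2034 lower; adjusted p = 0.068) and 0.076 in stimulated CD28ko-labelled against wild-type cells (1174 higher, 1029 lower; adjusted p = 0.15). In matched classes these were -0.154 (adjusted p = 0.32) and 0.028 (adjusted p = 0.47). Control heptamers were compared by the difference of means within length classes. Of 100, 1 gave as high a shift in stimulated T1792del cells, 3 as low in naive T1792tg and 4 as low in naive rescue cells. Rcan3, a published target, was higher in T1792del cells and lower with the transgene in both states and on both backgrounds.

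**Figure D4:**
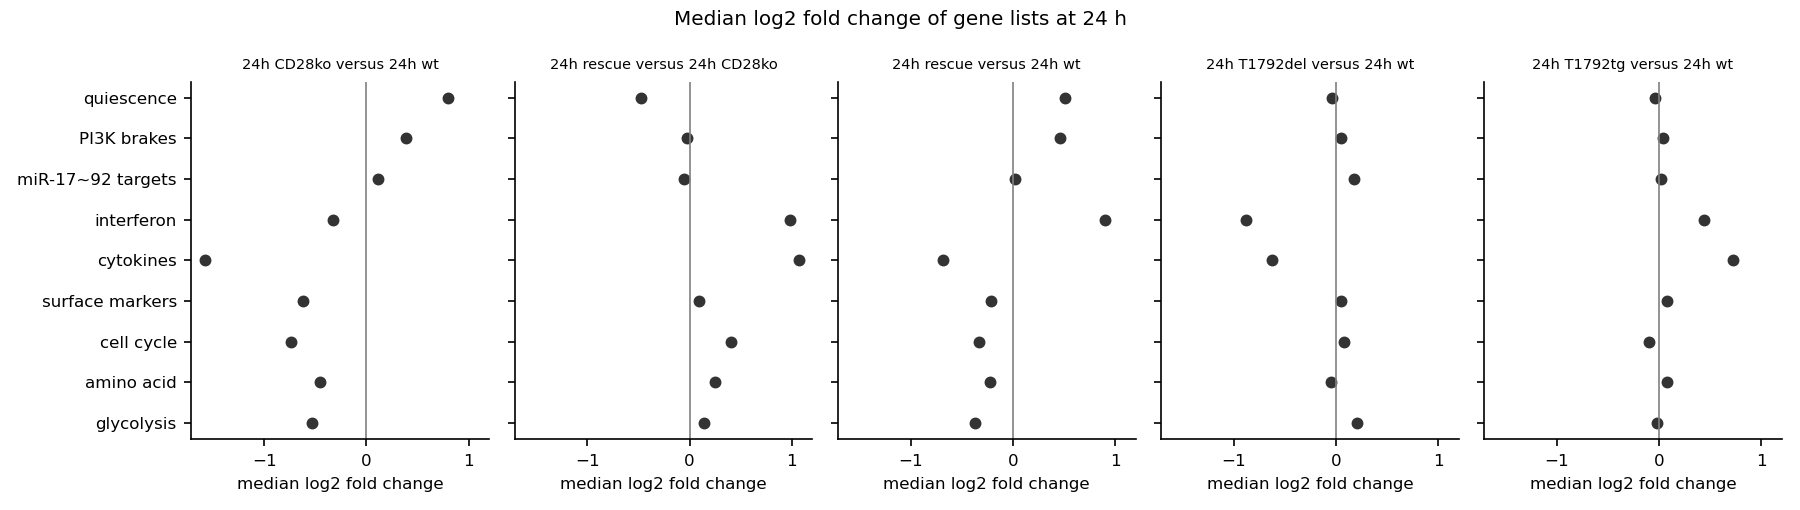
Median log2 fold change of the measured members of 9 gene lists in 5 comparisons at 24 h, as points, with lines at 0. The quiescence list lay at 0.8 in CD28ko-labelled against wild-type cells and at -0.48 in rescue against CD28ko-labelled cells.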

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

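All tests of explanations in this part, and the regroupings of libraries, were written down after the results were seen, while the interactions were chosen before.

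Mir17hg rose from 20.7 ± 2.44 to 172 ± 11.8 CPM in stimulated T1792del against wild-type cells and its response to stimulation differed from wild-type (log2 fold change 2.98 ± 0.18, adjusted p = 1.3e-13). The naive change was 0.08 on the log2 scale, so a host transcript altered by the engineering and counted alike in both states was not what was seen. That restates the interaction and is no separate test. Transgene libraries under the wrong label do not account for it either, since Gt(ROSA)26Sor read at least 10.6 CPM in every stimulated T1792del library and at most 0.347 CPM in those of T1792tg and rescue. The annotated interval of Mir17hg starts at 115044390, past the precursors Mir17 to Mir20a (115043671 to 115044263), so its count does not check their deletion. A change in how the host transcript is made or removed in stimulated cells stays open and was not tested.

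Gh, the growth hormone gene, was counted at 17.5 to 41.9 CPM in naive and 2.41 to 6.76 CPM in stimulated libraries of the Cre-bearing genotypes, and at most 0.33 CPM elsewhere. RNA of pituitary cells is argued against by prolactin (Prl), the partner hormone of that gland, with a pooled count of 0 in the 22 libraries with Cre, while the pituitary hormone gene Pomc had a mean of 0.958 CPM with and 0.849 CPM without Cre. A growth hormone sequence carried with the Cre transgene stays open: that all 22 libraries with Cre lay above the highest of the 16 without is the pattern itself and tests nothing. The labels do not describe the transgene's sequence, and why Gh was lower in stimulated than in naive libraries with Cre was not tested.

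Rpl29, a ribosomal protein gene whose reads near-identical copies share, read 1.56 and 1.83 CPM in naive T1792del 2 and 4. It read 80.3 and 89.9 CPM in 1 and 3 and 152 ± 27.2 CPM in naive wild-type. The neighbours Abhd14b and Dusp7 fell too, from 4.79 and 44.6 CPM in naive wild-type to 0.938 and 31.5 CPM in T1792del. Mislabelling is argued against by Gt(ROSA)26Sor, higher in all 8 T1792del libraries than elsewhere (at most 0.791 CPM). A difference inherited by some mice is possible, as all 4 numbers had the same class at both times. Chance gives that in 1 of 6 arrangements, so this stays open. No groups were formed by this gene.

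The response to stimulation differed from wild-type in 5905 genes of CD28ko-labelled, 833 of T1792del and 2185 of T1792tg cells, rescue differed from CD28ko-labelled cells in 1747 genes, and the transgene's effect at 24 h differed between backgrounds in 288 genes (edgeR interaction tests). Named genes in CD28ko-labelled cells were Tbx21 (-4.11), Sh2d1a (-3.47), Nt5e (3.69), Gucy1a1 (3.59), Il2ra (1.33), Pik3ip1 (2.76), Klf2 (2.84), Ccne2 (-2.40) and Fosb (4.14), as log2 differences. In T1792del cells they were Mir17hg (2.98), Ly6a (-2.23), Ly6c1 (-2.45), Irgm1 (-1.53) and Irf8 (-1.72). T1792tg cells differed in Plaur (1.90), Myo10 (1.82), Fasl (1.65), Dusp5 (0.91), Nrn1 (-1.97), Pdcd1 (-1.57), Nop58 (0.51) and Il7r (1.65). Rescue against CD28ko-labelled cells differed in Tbx21 (3.0), Il12rb2 (2.56), Irgm1 (1.99), Cd44 (1.48), Pdk2 (-1.83), Pglyrp1 (-1.86) and Mthfd1 (0.64). The transgene's effect differed in Tbx21 (2.96), Tbkbp1 (2.56), Ifitm3 (2.05), Lif (1.46), Irgm1 (1.46), Il7r (-1.71), Ahnak (-1.68) and Tcf7 (-0.58).

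Single libraries far from the other 3 of their group were sought for part of the genes named here, by the gap to the nearest value over the group's range (Dixon's criterion). Of 286 gene and group pairs, 14 stood apart, where chance gives about 1 in 20. P4ha2, Slc16a3 and Slc2a3, also apart in stimulated T1792del 2, are not among them. In CPM, the 14 included E2f1 in stimulated wild-type 4 (84.3, nearest 99.7), Bcl2 in naive T1792del 4 (322, nearest 254), Eomes in naive wild-type 3 (9.29, nearest 8.23), Lef1 in naive CD28ko-labelled 1 (473, nearest 561), Irgm1 in stimulated wild-type 2 (359, nearest 288), Jun in stimulated wild-type 2 (24.5, nearest 18) and Rcan3 in stimulated CD28ko-labelled 4 (57.4, nearest 61.5). The others, in CPM, were Sh2d1a in stimulated CD28ko-labelled 3 (6.19, nearest 7.29), Irf8 in naive T1792del 1 (26.7, nearest 43.4), Myo10 in naive T1792tg 3 (11.4, nearest 18), Pdk2 in stimulated CD28ko-labelled 3 (10.9, nearest 11.8), Tcf7 in stimulated T1792tg 3 (314, nearest 340), Maf in stimulated CD28ko-labelled 2 (4.53, nearest 7.35) and Lrrc32 in stimulated CD28ko-labelled 2 (5.26, nearest 4.1).

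Regrouping the libraries was used to ask whether chance can be excluded, in fits of the compared groups alone, and by the count of genes it can for every comparison but those named last. Only the real grouping, 1 of 35, gave as many genes, with the real count and the highest other given as a pair, in wild-type stimulation (10789, 0), CD28ko-labelled stimulation (10184, 0), T1792del stimulation (10703, 5), T1792tg stimulation (10678, 0), naive CD28ko-labelled (956, 32), naive T1792del (545, 24) and naive T1792tg (1913, 9). The same held among between-genotype comparisons at 24 h and interactions for stimulated CD28ko-labelled (7848, 0), stimulated T1792del (2592, 0), stimulated T1792tg (2631, 8), stimulated rescue against CD28ko-labelled (3851, 0), stimulated rescue against wild-type (6107, 7), the CD28ko-labelled interaction (6016, 0), the T1792del interaction (981, 0), the T1792tg interaction (2184, 0) and the rescue interaction (1480, 235). For stimulation in rescue cells the 10 regroupings are too few for a share under 0.05 (real count 9935, highest other 0). For naive rescue against naive CD28ko-labelled cells the count does not exclude chance. There 2 of 35 regroupings gave as many genes (real count 802, highest other 859, with CD28ko-labelled 1 among the rescue libraries). A second test, run only here and unadjusted for that, argues against chance by direction. The log2 fold changes of 12180 genes correlated at 0.631 with those of naive T1792tg against wild-type (no shared library). Only this grouping, 1 of 35, gave as much (highest other 0.45). Genes are not independent replicates. For the transgene's effect on both backgrounds 2 of 100 regroupings gave as many genes (real count 929). A regrouping that kept the rescue libraries together and mixed T1792tg with wild-type libraries gave 1350. Regrouping within each background also breaks up a transgene effect that both share, so it cannot exclude chance for the difference between backgrounds. The stimulation interactions have the same limit, since their regroupings mixed genotypes in both states.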

How the results depend on the processing

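The tests with female libraries alone, without naive CD28ko-labelled 1 and naive rescue 2, and with genes away from the engineered loci were chosen after the results were seen; the other alternatives were planned. The counts of the 19 comparisons stayed within 1.5 times their value with RLE size factors, both other filters, the replicate block, the sex term and genes away from the loci, and so did the 9 stimulation and interaction counts for which a block within genotype could be fitted. The labels do not say that equal numbers link libraries; all 19 pairs of equal number within a genotype had the same sex, and the naive library of 16 of them correlated best with the stimulated library of its own number after group means were removed (r from 0.025 to 0.342), while the mean r of equal numbers across genotypes ran from -0.039 to 0.041. The block within genotype gave 5816, 727 and 1983 genes for the CD28ko-labelled, T1792del and T1792tg interactions and 1543 for that of rescue. A count with the replicate block over all groups was 7032 for CD28ko-labelled against wild-type and 241 for the transgene on both backgrounds. Picked for size or p, the 174 named-gene results were likely to hold. All kept direction and call with RLE size factors, DESeq2, no low-count filter, the replicate block and the compared groups alone. All did so without naive CD28ko-labelled 1 and naive rescue 2. So did the 165 with the stricter filter, 164 away from the loci and 54 with the block within genotype. The sex term ended the call of Hba-a2 in stimulated T1792del cells (2.24). Without 1 library, 1617 of 1629 values kept direction and call. The other 12 were Hba-a2 (2.19 to 2.92) and Gzma (1.02 to 1.32) in stimulated T1792del cells. Female libraries alone ended the call of 5, Hba-a2 (1.04) and Gzma (1.21) in stimulated T1792del, Rcan3 in stimulated T1792tg (-0.31) and the T1792tg interactions of Nop58 (0.42) and Il7r (1.59), with a single T1792tg library left per group.

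With the compared groups alone, counts moved to 956 for naive CD28ko-labelled, 1913 for naive T1792tg, 802 for naive rescue, 2631 for stimulated T1792tg, 3851 for stimulated rescue against CD28ko-labelled cells and 929 for the transgene on both backgrounds; the cause was not tested. Female libraries alone gave 397 in naive and 672 in stimulated T1792del, 518 in naive and 221 in stimulated T1792tg, 141 and 69 for their interactions and 30 for both backgrounds, with fewer libraries by construction. DESeq2 gave 1251 for the T1792del interaction and 522 for both backgrounds, and leaving out naive CD28ko-labelled 1 and naive rescue 2 gave 487 for the latter; the cause was not tested. RLE size factors moved the median of all genes in wild-type stimulation from -0.063 to -0.122, and DESeq2 gave -0.144. Leaving out 1 library gave 1170 to 2188 for naive CD28ko-labelled, 439 to 786 for naive T1792del, 1388 to 2278 for stimulated T1792del, 962 to 1710 for stimulated T1792tg, 1300 to 2561 for stimulated rescue against CD28ko-labelled, 443 to 1007 for the T1792del interaction, 1000 to 2152 for the rescue interaction and 119 to 447 for both backgrounds, each with fewer libraries.

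List calls numbered 189 as planned. With an estimated correlation (0.02 to 0.078 for seeds, above the set 0.01) they were 41, all among these. Fry gave 237, 169 shared, and the block 196, 189 shared. Seed shifts had an adjusted p of 0.16 in stimulated T1792del, 0.16 in naive T1792tg and 0.18 in naive rescue cells with an estimated correlation; with 8mer sites alone, all families pooled, stimulated rescue against CD28ko-labelled cells (0.021, and 0.33 with an estimated correlation) and wild-type stimulation (0.019, and 0.32 with an estimated correlation) passed as well; the cause was not tested. By single family, 8mer sites of miR-18 passed in stimulated T1792tg against wild-type cells, where such genes lay higher by 0.07 (0.021, and 0.3 with an estimated correlation), the opposite of what added microRNA predicts. In stimulated CD28ko-labelled against wild-type cells those of miR-18 (0.017, and 0.3 with an estimated correlation) and miR-92 (0.031, and 0.55 with an estimated correlation) passed. Single families also passed in wild-type stimulation, naive T1792tg, naive rescue, stimulated T1792del and stimulated rescue cells, none with an estimated correlation (lowest adjusted p = 0.058). The 1986 genes that moved oppositely in rescue were 1101 at a threshold of 0.01 and 1133 with divided CD28ko-labelled libraries, both stricter by construction. Depth limits genes with few counts, such as Mir17 outside the transgene groups.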

Other observations

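The tests of the hypothesis in this part were chosen after the results were seen.

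Helper lineage and memory genes moved in both directions in stimulated CD28ko-labelled against wild-type cells (4 against 4 libraries). Maf, a factor of interleukin-4 and interleukin-10 producing T cells, rose from 1.08 ± 0.0706 to 6.85 ± 1.56 CPM (log2 fold change 2.67 ± 0.22, adjusted p = 2.5e-12), and Bcl6, the factor of follicular helper cells, rose (0.94 ± 0.11), while Il12rb2 fell (-2.93 ± 0.23). Of the helper lineage list, 5 of 16 genes were higher and 6 lower (5 and 6 adjusted over the list alone; adjusted p = 0.92). The memory list had 3 of 13 higher and 3 lower (3 and 3 adjusted over the list alone; adjusted p = 0.81), with the scaffold protein gene Ahnak (2.15 ± 0.19) and the interleukin-18 receptor gene Il18r1 (2.48 ± 0.19) higher and the integrin gene Itgb1 (-1.07 ± 0.07) lower. In stimulated rescue against CD28ko-labelled cells (3 against 4 libraries) Itgb1 rose (0.53 ± 0.08), and the memory list had 6 of 13 higher and 2 lower (6 and 3 adjusted over the list alone; adjusted p = 0.0095, and adjusted p = 0.24 with an estimated correlation).

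Death and calcineurin genes also moved there. Nfatc1, a factor that calcineurin activates, rose from 216 ± 4.77 to 390.4 ± 12.8 CPM (log2 fold change 0.86 ± 0.08, adjusted p = 1.4e-11) in stimulated CD28ko-labelled cells, with Ppp3cc, a calcineurin subunit (0.90 ± 0.10), and the death receptor gene Fas (0.75 ± 0.11). The apoptosis list had 6 of 16 higher and 6 lower (6 and 6 adjusted over the list alone; adjusted p = 0.92). Of the regulatory T cell markers 4 of 10 genes were higher and 5 lower (4 and 5 adjusted over the list alone; adjusted p = 0.92), with Capg, an actin-capping protein, at 1.52 ± 0.11, Nrp1 at 1.28 ± 0.16 and Lrrc32 at -1.48 ± 0.17. In rescue against CD28ko-labelled cells Nrp1 rose further (1.10 ± 0.16) and Lrrc32 rose (1.54 ± 0.17).

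A hypothesis is that CD28ko-labelled cells made a weaker or slower move along the same stimulation response. It was tested against the response of T1792tg cells, which share no library with the comparison of CD28ko-labelled with wild-type cells at 24 h. Of 6403 genes called in both, 5742 (89.7%, 95% Wilson interval 88.9 to 90.4%) moved against the stimulation direction, where a level of 50% would argue against it; genes are not independent replicates, so the interval is too narrow. The T1792del response gave 87.8%. This is consistent with a weaker or slower move, and 661 genes that moved with the stimulation direction are left outside it. Genes whose level rises and falls within 24 h cannot be placed by 2 time points, and the difference between weaker and slower was not tested.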
